A study of Mus musculus with 17 samples.

How the data were processed

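RNA was profiled in 17 libraries of the E14 line of mouse embryonic stem cells (ESCs). In 6 libraries, cells kept in serum with leukemia inhibitory factor (LS) or in 2i medium carried 1 of 2 short hairpins against Esrrb or an empty vector (shEV). The 2i medium held CHIR at 15 µM and PD0325901 at 5 µM, inhibitors of GSK3 and of the kinase MEK. The other 11 libraries held Esrrb hairpins and an empty vector in extended potential stem cells (EPSCs; CHIR at 3 µM, PD0325901 at 1 µM and further inhibitors), Yy1 hairpins and an empty vector whose title names no medium, and CRISPR interference with scrambled guides (sgScrmbl, 2 libraries) or guides titled sgMIR (3 libraries). Per the labels' protocols, plasmids were introduced with Lipofectamine, cells were harvested 3 days later, RNA was taken up in Trizol, and libraries were made with a stranded poly(A) kit. The labels do not say whether libraries of a group come from separate cultures, so every p-value measures the spread between these samples only.

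Per the submitters' processing notes, reads were aligned with STAR to the mm9 genome build and gene values were made with Cuffnorm. The versions are not given in the sources used here. The deposited values are FPKM, fragments per kilobase of transcript per M mapped fragments, in 2 tables of 24819 genes each, 1 with the 6 LS and 2i libraries and 1 with the other 11. Each table was normalized by the authors on its own, so values of the tables were never tested against each other. Counts were not used here. 1 column that belongs to no listed sample was not used. The tables give gene symbols without positions, and no coordinates are printed.

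The depth is not stated. It was estimated from the spacing of low values: among genes at 0 in at least as many of a table's libraries as above 0, the most frequent product of FPKM and transcript length was taken as 1 fragment. That gave 12.0 to 16.4 M fragments (M, mega) per library (median 13.9) for the LS and 2i table and 0.232 to 0.364 M (median 0.286) for the other, a ratio of medians of 48.4. For a transcript of 2 kb, 1 fragment then corresponds to 0.030 to 0.042 FPKM in the first table and to 1.37 to 2.16 FPKM in the second. These depths are estimates and serve for orientation only, and whether the shallower table holds all reads of its libraries is not stated in the sources used here. Transcript lengths came from GENCODE vM21, matched by symbol for 98.1% of the genes of each table (99.2% and 98.8% of the genes tested), and were used for lengths alone.

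Genes with at least 1 FPKM in at least 2 libraries of a table were tested, 12347 in the LS and 2i table and 13800 in the other. Values were taken as log2(FPKM + 1). A linear model with 1 mean per group was fitted to each table with limma 3.58.1 in R 4.3.3, with a mean-variance trend. Contrasts were tested two-sided with limma's moderated test, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. "Rose" and "fell" below mean an adjusted p under this threshold. The 8 comparisons were Esrrb knockdown in LS, in 2i and in EPSCs, the difference between the responses in 2i and LS, 2i against LS (mean of the 3 libraries of each medium, with the same constructs), Yy1 knockdown, sgMIR against sgScrmbl, and the EPSC empty vector against the empty vector without a named medium. Each knockdown has 1 control library, which the model assumes to vary like the hairpin pairs. The last comparison sets 1 library against 1 library, has no replicate check of its own and borrows its spread from the other groups.

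Of 28 gene lists, 27 could be tested in each comparison with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera was repeated with an estimated correlation and limma's fry was run beside it. With the estimated correlation, no list reached an adjusted p under 0.05 in any comparison. That version rests on few residual degrees of freedom (2 in the LS and 2i table, 5 in the other) and has little power. A list that misses it is therefore neither supported nor contradicted by it. For members of a list, counts were also adjusted over the list alone. Lists, tests, the rule for named genes and most alternatives were chosen before the data were examined. The rule names the target gene, the 8 largest rises and 8 largest falls past the threshold with the same sign in every library (leaving out predicted genes, clones, ribosomal and histone copies), and up to 4 called members per list. Where no member of a list passed, its 2 largest changes are given as values. Where no gene passed at all, the 5 largest changes each way at an unadjusted p under 0.05 are given. Some genes that the rule names are not reported here. Correlations between comparisons are across genes, which are not independent replicates.

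The steps were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold per comparison. Every simulated gene had the same spread beyond counting noise, without hairpin differences, and low genes were not changed. Recovery in the real data may therefore be lower. At 2-fold, 95% were recovered for Esrrb knockdown in 2i, 97% in LS and 100% for 2i against LS, and at 4-fold 100% in each. For the shallower table, 1% and 28% were recovered for EPSCs at 2-fold and 4-fold, 1% and 17% for Yy1, and 11% and 60% for sgMIR. False calls made up 6.25%, 7.94%, 9.09%, 23.7%, 5.26% and 11.2% of the simulated calls in the same order of comparisons.

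Alternatives were a pseudocount of 0.1, no filter, a filter at FPKM 5, quantile normalization, median centring, robust variance estimation, an additive model, a block for the hairpin number, fits to the compared groups only, a term for the 2 title formats of the guide libraries, subsets of the sgMIR libraries, and leaving out each library of a group with at least 2. The 2i libraries were also set against the LS libraries within each construct, as values with no test. That step, a filter at FPKM 20, library quality weights, leaving out each empty vector from 2i against LS, and testing the genes changed in LS and 2i as sets in the other table were chosen after seeing the data. Figures and depth estimates were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.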

Results

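Transcript levels were measured by RNA-seq in 17 libraries of mouse E14 cells that fall into 10 groups of 1 to 3 libraries. The series asks how Esrrb, an orphan nuclear receptor of the pluripotency network, and MIR elements, an old family of short interspersed repeats, shape expression across pluripotent states. A first set of 6 libraries covers LS and 2i medium, each with 1 empty-vector library and 2 Esrrb hairpin libraries, at an estimated 12.0 to 16.4 M fragments (M, mega). A second set of 11 libraries covers EPSCs, Yy1 knockdown and CRISPR interference, at an estimated 0.232 to 0.364 M fragments. Between 29.3% and 31.3% of the 24819 genes were listed at 0 in libraries of the first set and 48.5% to 54.9% in the second. Libraries of a group correlated across genes at 0.991 to 0.993 in the first set and 0.827 to 0.878 in the second. In the second set libraries of different groups reached like values, such as 0.877 between 1 sgScrmbl and 1 sgMIR library. All values are FPKM, and fold changes are log2 with their standard error (SE).

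Esrrb transcripts were reduced in every Esrrb hairpin library. In 2i, the level was 273 FPKM with the empty vector and 30.4 and 43.0 FPKM with the hairpins, or 11.1% and 15.7% of the control (log2 change -2.88, SE 0.46, adjusted p = 0.022). In LS, it was 210 FPKM with the empty vector and 23.9 and 59.1 FPKM with the hairpins, or 11.4% and 28.1% (log2 change -2.45, SE 0.46, adjusted p = 0.025). In EPSCs, it was 45.7 FPKM with the empty vector and 0.648 and 12.3 FPKM with the hairpins (log2 change -3.32, SE 1.04, adjusted p = 0.36, which did not pass). Yy1 was at 53.5 FPKM in its control and at 36.5 and 20.5 FPKM in the hairpin libraries, 68.3% and 38.3% of the control (log2 change -0.94, SE 0.49, adjusted p = 0.70). Esrrb was at 82.7 and 62.0 FPKM with scrambled guides and at 33.9, 70.6 and 86.9 FPKM with sgMIR guides. Without either hairpin library of 2i, the adjusted p for Esrrb in 2i was above the threshold (0.088 without replicate 1, 0.060 without replicate 2). With no filter on low values it was 0.16 in 2i and 0.13 in LS, and with robust variances 0.23 and 0.19.

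**Figure D1:**
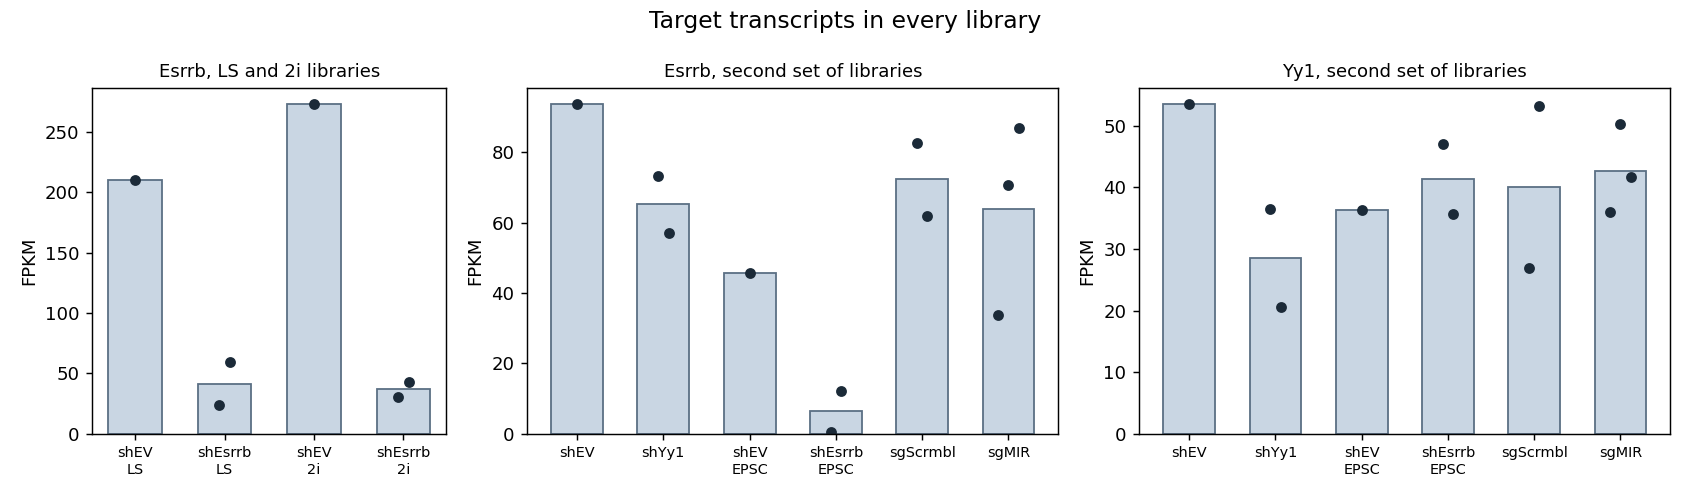
Esrrb and Yy1 transcript levels (FPKM, vertical axes) in each library; bars are group means, points are libraries, and groups of 1 library show that library alone. Esrrb hairpin libraries sit at 23.9 to 59.1 FPKM in LS and 2i against 210 and 273 FPKM in the controls, and Yy1 hairpin libraries at 20.5 and 36.5 FPKM against 53.5 FPKM.

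Esrrb knockdown in LS lowered naive pluripotency genes and raised genes of the formative and primed state, the next step of development. Of 25 naive genes, 14 fell and 1 rose (15 and 2 adjusted over the list alone). Tfcp2l1, a transcription factor of the naive network, went from 73.1 to 14.8 and 20.4 FPKM (log2 change -2.01, SE 0.20). The naive factors Tbx3 and Klf4 went from 34.3 to 6.76 and 9.14 FPKM (-1.99, SE 0.16) and from 70.0 to 15.4 and 23.3 FPKM (-1.83, SE 0.23). Klf2, named here after its values were seen, was the member that rose (log2 change 0.79). Of 19 formative and primed genes, 9 rose and none fell (13 and 1 adjusted over the list alone). The Nodal antagonist Lefty1 rose from 38.4 to 231 and 288 FPKM (log2 change 2.72, SE 0.19). Car4 (1.44, SE 0.29), Lef1 (1.25, SE 0.26) and Sall2 (1.25, SE 0.15) rose with it. Camera gave an adjusted p of 4.1e-06 for each list, with medians of -0.79 and 0.63, and adjusted p = 0.53 for each with an estimated correlation. Among members of the core pluripotency list Nanog fell from 409 to 241 and 258 FPKM (log2 change -0.71, SE 0.08), while Lin28a (0.87), Sall4 (0.76) and Tcf3 (0.39) rose.

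Energy metabolism genes were also lower in LS after Esrrb knockdown. Of 77 oxidative phosphorylation genes, 20 fell and none rose (38 fell adjusted over the list alone). Cox7a1 fell from 47.1 to 14.2 and 10.8 FPKM (log2 change -1.84, SE 0.17), with Ndufb4 (-0.83), Uqcrb (-0.67) and Cox5a (-0.65). Of 23 glycolysis and hypoxia genes, 4 fell (15 adjusted over the list alone): Vegfa (-1.68), the glycolytic enzymes Hk1 (-1.58) and Pfkp (-1.57), and the glucose transporter Slc2a3 (-0.56). The list medians were -0.26 and -0.56, with adjusted p = 9.2e-15 and 3.5e-06 by camera and adjusted p = 0.53 and 0.80 with an estimated correlation. Cholesterol synthesis also had a low median (-0.25, adjusted p = 0.013, and adjusted p = 0.81 with an estimated correlation), where Msmo1, Pmvk and Stard4 fell.

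The largest falls in LS were Kdelr3, from 42.8 to 3.20 and 4.12 FPKM (log2 change -3.24, SE 0.18), the lactate dehydrogenase subunit Ldhb, from 536 to 57.9 and 118 (-2.68, SE 0.37) and the connexin Gjb5 (-2.60). Further large falls were the fatty acid binding protein Fabp3 (-2.48), Gprc5a (-2.40), Crxos (-2.36), the growth factor Bmp4 (-2.31) and Crtac1 (-2.29). The largest rises after Lefty1 were Nkx2-9 (2.60), the GTPase Irgm1 (2.38), Raet1a (2.35) and Ccno (2.16). They were followed by the hormone precursor Trh, from 286 to 1462 and 1022 FPKM (2.09, SE 0.30), Hsd11b2 (2.09) and the imprinted RNA H19 (2.09). The de novo methyltransferase Dnmt3b (1.05) and its cofactor Dnmt3l (0.61) rose, while the demethylating enzyme Tet2 (-1.19) and the imprint regulator Zfp57 (-1.13) fell. In total 1213 of 12347 genes changed, 573 higher and 640 lower, and 3668 had an unadjusted p under the threshold. With no filter 1 gene passed, which is not among these, and with a block for hairpin number 2804 did. The majority depends on scaling: quantile normalization gave 520 higher and 495 lower. Without hairpin replicate 1 the count was 371, and without replicate 2 it was 1145. Of the 83 named genes that passed, 54 and 73 still did.

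Esrrb knockdown in 2i raised genes of the two-cell-like state, a rare state that resembles the early embryo. Of 20 such genes, 15 rose and none fell (18 adjusted over the list alone). Zscan4d rose by 3.28 (SE 0.21) and Usp17lb went from 7.02 to 69.0 and 56.3 FPKM (log2 change 2.98, SE 0.21). Zscan4b rose by 2.72 (SE 0.27) and Zscan4f by 2.71 (SE 0.20). The list median was 1.92 (camera adjusted p = 3.0e-17, and adjusted p = 0.50 with an estimated correlation). These families hold near-identical copies whose reads cannot be assigned with certainty, so the values of single copies are uncertain. In LS, 9 of the same 20 genes rose (10 adjusted over the list alone), with a median of 0.72 (adjusted p = 6.0e-07, and adjusted p = 0.80 with an estimated correlation). Usp17lb (1.53), Tdpoz4 (1.44), Zscan4d (1.32) and Usp17le (1.15) were the largest there.

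Naive genes were lower in 2i as well, in a smaller number. Of 25, 6 fell and 1 rose (7 and 2 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 0.0049, and adjusted p = 0.50 with an estimated correlation). Nr0b1, a corepressor of the pluripotency network, went from 61.4 to 10.0 and 12.2 FPKM (log2 change -2.38, SE 0.17). Tcl1 went from 129 to 30.3 and 30.7 (-2.04, SE 0.12) and Jam2 from 115 to 33.1 and 39.3 (-1.65, SE 0.23). Klf4 went from 89.8 to 32.8 and 40.3 FPKM (-1.28, SE 0.23), while Gbx2 rose (1.29, SE 0.26). Of 19 formative and primed genes, Lefty1 (2.07), Lefty2 (1.16) and Dnmt3a (0.86) rose. Otx2, a factor of the formative state, fell from 12.1 to 2.23 and 1.98 FPKM (log2 change -2.08, SE 0.23). Adjusted over the list alone 4 and 1 passed, and the list did not pass camera (adjusted p = 0.073). Among core factors Dppa2 (1.36) and Lin28a (0.42, named after its values were seen) rose, and Utf1 (-1.03) and Sox2 (-0.68) fell.

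Oxidative phosphorylation genes were lower in 2i too: 9 of 77 fell and none rose (14 fell adjusted over the list alone). Cox7a1 (-1.90), Cox6a2 (-0.98), Ndufb4 (-0.66) and Cox5a (-0.56) fell most, and the list had a median of -0.16, camera adjusted p = 1.2e-11 and adjusted p = 0.50 with an estimated correlation. Of 13 interferon response genes, Isg15 (3.30), Oasl1 (1.83) and Cxcl10 (1.17) rose and Oas1a (-0.86) fell (6 and 2 adjusted over the list alone). Their median was 0.46, adjusted p = 0.013 and adjusted p = 0.51 with an estimated correlation. The largest falls in 2i were the uridine phosphorylase Upp1, from 293 to 24.2 and 26.2 FPKM (log2 change -3.49, SE 0.36), the surface protein Ly6a (-3.12) and Ly6g6e (-2.99). They were followed by Khdc3 (-2.76), the adenylate kinase Ak4 (-2.66), Nr0b1, the chromatin remodelling subunit Smarcd3 (-2.15) and Gjb5 (-2.13). The largest rises beside the Zscan4 and Usp17 copies were Pisd-ps1 (3.57), Isg15, the cyclin Ccnd2 (3.26) and Irgm1 (3.04). In total 592 of 12347 genes changed, 325 higher and 267 lower, and 2373 had an unadjusted p under the threshold. With no filter 5 genes passed and with a block for hairpin number 1466. The majority depends on scaling: median centring gave 244 higher and 299 lower. Without hairpin replicate 1 the count was 221 and without replicate 2 it was 236. Of the 59 named genes that passed, 26 and 31 still did.

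Further lists passed camera. In 2i these were Wnt and beta-catenin targets (0.58, adjusted p = 0.019, with Tnfrsf19 risen by 0.81), immediate early genes (0.34, adjusted p = 0.013, with Jun, Ier5 and Nr4a1 risen) and histones (0.22, adjusted p = 0.029). With lower medians they were the integrated stress response (-0.18, adjusted p = 0.013, with Asns fallen by 0.57), G2 and M phase (-0.10, adjusted p = 0.013), S phase (-0.086, adjusted p = 0.028) and ribosomal proteins (-0.085, adjusted p = 7.4e-05). With an estimated correlation their adjusted p were 0.50, 0.50, 0.69, 0.50, 0.65, 0.50 and 0.66. In LS these were p53 targets (0.14, adjusted p = 0.042, with Pltp and Epha2 risen), G2 and M phase (-0.17, adjusted p = 0.037) and ribosomal proteins (-0.086, adjusted p = 0.027), at adjusted p = 0.80, 0.80 and 0.83 with an estimated correlation. Under quantile normalization the ribosomal protein medians were -0.019 in each medium, and that of S phase in 2i was -0.037. Fibroblast markers, of which 5 were tested, did not pass camera in either medium (adjusted p = 0.22 in 2i and 0.82 in LS), and Thy1 fell in LS (-0.81).

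The responses of both media overlapped. Among 12346 genes without Esrrb, 97 rose in both media and 149 fell in both, where independent lists would share 15.1 and 13.8, and 6 went opposite ways, where 29.2 would. Log2 changes correlated across genes at 0.48 (Pearson) and 0.42 (Spearman). The difference between the responses, tested as an interaction, passed for 13 genes, 6 of them higher in 2i, and 1818 had an unadjusted p under the threshold. Zfp57, which protects imprints, fell in LS from 168 to 74.8 and 77.5 FPKM but was at 274, 288 and 263 FPKM in 2i (difference 1.14, SE 0.12, adjusted p = 0.043). Ptch1, the Hedgehog receptor, was at 17.8 FPKM in the LS control and 87.8 and 68.6 FPKM with hairpins, and at 6.89, 6.57 and 6.23 FPKM in 2i (difference -2.16, SE 0.22, adjusted p = 0.038). The others named were Pisd-ps1 (3.59), the myosin light chain Mylpf (1.85), the phosphatase Acp6 (1.44), Spats2l (-2.26), Bend3 (-1.50) and Rnf7 (-1.12). Esrrb itself did not differ between media past the threshold (difference -0.44, SE 0.65, adjusted p = 0.79). In the 4 fits that leave out 1 hairpin library, a group keeps 1 library. The named genes that had passed and were tested there kept their direction in each fit. Most of them lost their call without either hairpin library of 2i. Mylpf stayed past the threshold in all 4 fits. With a block for hairpin number, since both media carry the same hairpins, 637 genes passed, 394 of them higher in 2i. That fit had 12.3 total degrees of freedom, mostly from limma's prior, against 6.84 in the main fit. Hairpin differences correlated across genes at 0.18 between the media, so the larger count may rest on the prior.

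Of the lists, the two-cell-like genes had a median difference of 1.13 (camera adjusted p = 4.9e-08; 11 of 20 higher in 2i adjusted over the list alone). Zscan4d was at 1.96 and Zscan4c at 1.90, neither past the all-gene threshold (adjusted p = 0.074 and 0.14). Naive genes had a median difference of 0.44 (adjusted p = 0.032; 6 higher and 3 lower adjusted over the list alone). Formative and primed genes had -0.54 (adjusted p = 5.2e-04; 2 lower adjusted over the list alone), with Otx2 at -1.91 and Car4 at -1.26. The 6 mesoderm and primitive streak genes had 0.94 (adjusted p = 0.032; 3 higher adjusted over the list alone), with Cdx1 at 2.67 and Eomes at 1.38. Glycolysis and hypoxia genes had 0.32 (adjusted p = 9.4e-04; 3 higher adjusted over the list alone), with Vegfa at 1.62 and Bnip3 at 1.24. Oxidative phosphorylation had 0.086 (adjusted p = 0.032), with Cox8c at 1.24 and Cox6a2 at -0.90. With an estimated correlation the adjusted p was 0.86 for glycolysis and hypoxia and 0.73 for the other 5 lists.

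**Figure D2:**
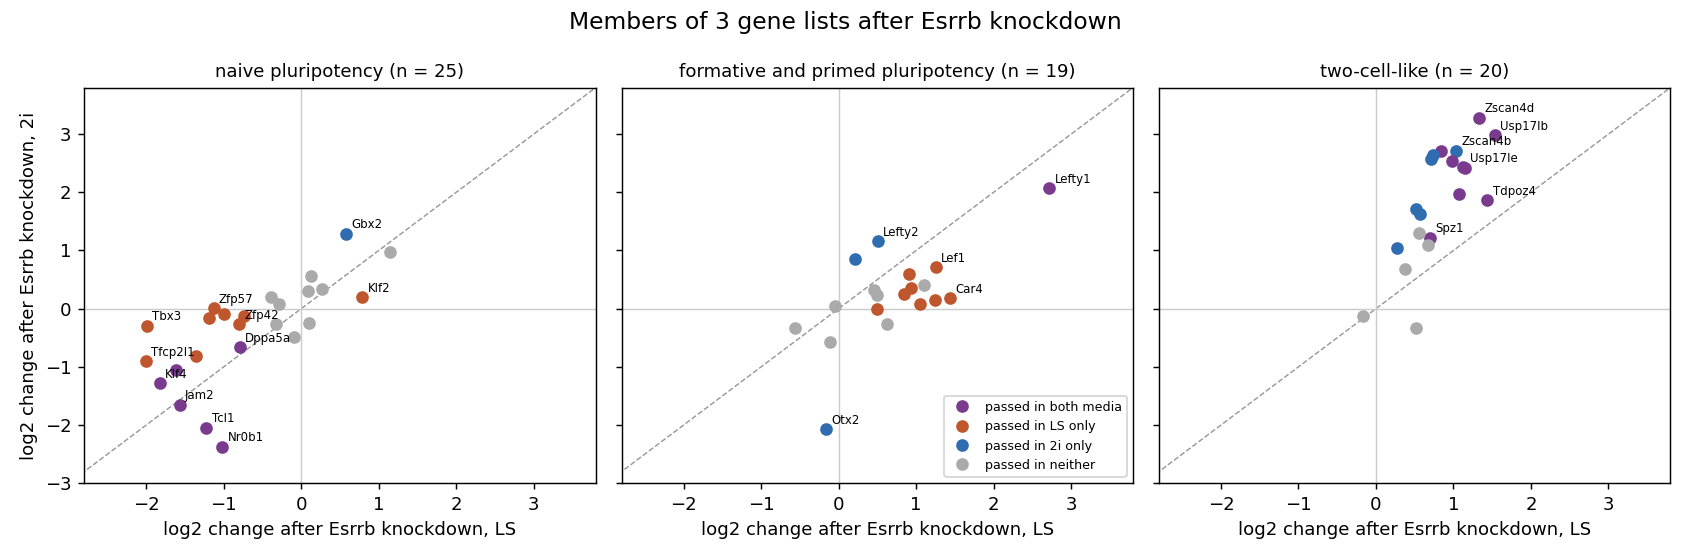
Log2 change after Esrrb knockdown in LS (horizontal) and in 2i (vertical) for each tested member of the naive, formative and primed, and two-cell-like lists; points are genes, colours show the media in which the gene passed the test, and the dashed line marks equal change. Zscan4d lies at 1.32 in LS and 3.28 in 2i, and Tbx3 at -1.99 in LS and -0.29 in 2i.

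The comparison of 2i with LS, over 3 libraries per medium of which 2 carry Esrrb hairpins, gave the most changed genes of the series. Naive factors were higher in 2i: of 25 genes 14 rose and 7 fell. Tbx3 (log2 change 2.63, SE 0.11), Tfcp2l1 (2.09, SE 0.13) and Jam2 (1.68, SE 0.15) rose, while Dppa3 fell (-1.57, SE 0.26). These genes differed by 1.49, 1.35, 1.735 and -1.45, in that order, between the empty-vector libraries alone. Of 19 formative and primed genes 13 fell, including Lefty1 (-4.56, SE 0.13), Lefty2 (-3.20), the growth factor Fgf15 (-2.89) and the claudin Cldn6 (-2.12). Foxd3 (1.38) and Nodal (0.82), named after their values were seen, rose. The ERK pathway, which the MEK inhibitor of 2i blocks, had 11 of 17 targets lower, among them Egr1 (-2.62), Spry4 (-2.36), Dusp6 (-1.68) and Dusp4 (-1.57). Of 6 mesoderm and primitive streak genes 5 rose, with Cdx1 (2.14), Eomes (1.30), Snai1 (1.07) and Msx2 (1.03) the largest. Between the empty-vector libraries alone Cdx1 differed by 0.36 and Eomes by 0.37, and between the hairpin libraries by 3.03 and 1.76. Glycolysis and hypoxia genes were lower (17 of 23 fell), with Egln3 (-3.05), Bnip3 (-2.74), Pdk1 (-2.20) and Ndrg1 (-1.92).

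In 2i 68 of 85 ribosomal protein genes fell (median -0.28, or -0.073 under quantile normalization, with Rpl22 at -0.61). Also lower were 26 of 38 histone genes (median -0.78, with Hist1h1d at -1.70) and 15 of 20 G2 and M phase genes (median -0.34, with Bub1 at -0.78). Of two-cell-like genes 12 of 20 rose over all libraries, with Tdpoz3 (1.07) and Usp17lb (0.98). The rise was not seen between the empty-vector libraries, where the list median was -0.012, Tdpoz3 differed by 0.033 and Usp17lb by 0.011. Between the hairpin libraries the median was 0.68. Without hairpin replicate 1 of 2i, Usp17lb was at 0.41 with adjusted p = 0.078. Among core factors Nanog rose (1.03) and Utf1 (-2.14), Lin28a (-1.30) and Tdgf1 (-1.14) fell. Of 12 genes of the DNA methylation machinery, Zfp57 (1.46), Tet2 (1.41) and Prdm14 (1.30) rose and Dnmt3a fell (-0.91). Between the empty-vector libraries alone Zfp57 differed by 0.70, Tet2 by 0.72, Prdm14 by 1.05 and Dnmt3a by -1.34. Of 19 germline genes silenced by methylation Dazl (2.08) and Tuba3a (2.04) rose most. The largest rises were Crxos (3.73), Trpm1 (3.52), Meis2 (3.32), Il34 (3.18), Calcoco2 (3.10), Oasl1 (3.10), Snx20 (3.09) and Plagl1 (2.96). The largest falls after Lefty1 were Id2 (-3.87), Spink1 (-3.48), Rprl3 (-3.35), Lefty2, Egln3, Fgf15 and Dmrt1 (-2.83).

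In this comparison 6823 of 12347 genes changed, 3671 higher and 3152 lower, and 934 by more than 2-fold. The majority depends on scaling: median centring gave 3014 higher and 3825 lower, and quantile normalization 3269 and 3337. Between the 2 empty-vector libraries alone, which are also part of the comparison, the medians were 0.29 for naive, -0.74 for formative, 0.40 for mesoderm, -0.49 for ERK, -0.98 for glycolysis, -0.27 for ribosomal, -0.94 for histone and -0.31 for G2 and M phase genes. Adjusted over the list alone, the counts of naive (14 and 7), formative (2 and 13), ERK (3 and 11), mesoderm (5 and 0), histone (2 and 26), G2 and M phase (0 and 15) and two-cell-like genes (12 and 0) were the same, higher and lower in that order. Those of glycolysis (3 and 18) and ribosomal proteins (4 and 70) were nearly so. Camera adjusted p were 3.6e-11 for ribosomal proteins, 5.0e-06 for histones, 1.6e-05 for glycolysis, 1.5e-04 for G2 and M phase, 4.4e-04 for formative genes, 0.0042 for ERK, 0.019 for mesoderm, 0.039 for naive and 0.045 for two-cell-like genes. With an estimated correlation they were 0.71 for two-cell-like genes and 0.57 for the other 8 lists.

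Esrrb knockdown in EPSCs, in the shallower set, passed the test for 5 of 13800 genes, 3 higher and 2 lower, and 1343 had an unadjusted p under the threshold. The balance depends on the settings: a pseudocount of 0.1 gave 70 higher and 9 lower, and a fit to the compared groups only 66 higher and 3 lower. Echdc2, an enoyl-CoA hydratase family member, fell from 343 to 39.9 and 53.3 FPKM (log2 change -2.87, SE 0.31, adjusted p = 0.043). Rex1bd (28.1 and 65.0 FPKM), Ubald1 (13.7 and 18.0) and Gtf2h5 (9.83 and 11.6) were listed at 0 in the EPSC control. The predicted gene Gm4632, named after its values were seen, was at 20.7 FPKM there and listed at 0 in both hairpin libraries. Leaving out either hairpin library, no gene passed with limma, and the adjusted p of Echdc2 was 0.28 without replicate 1 and 0.27 without replicate 2. Ribosomal proteins had a median of 0.72 (77 of 84 above 0; camera adjusted p = 2.9e-11, and adjusted p = 0.92 with an estimated correlation), with 3 members higher adjusted over the list alone and none over all genes. Rpl34 was at 5.97 FPKM in the control and at 199 and 101 FPKM with hairpins (adjusted p = 0.15), and Rps21 had a log2 change of 3.56 (adjusted p = 0.15). Against the ESC control, the ribosomal protein median was -0.92 in the EPSC control library and -0.02 and -0.41 in the hairpin libraries, so the single control was the low one. The median change over all genes was 0.096 and moved by -0.22 under median centring, and 0 genes passed with limma after centring; the cause of that loss was not tested.

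Yy1 knockdown passed the test for 0 of 13800 genes with limma. A pseudocount of 0.1 gave 16 higher and 7 lower, and a fit to the compared groups only 30 higher and 14 lower. In the main fit 1060 genes had an unadjusted p under the threshold, and the smallest adjusted p was 0.098. The largest falls at that level, none past the adjusted threshold, were of Lefty1 (48.8 FPKM in the control), Fitm1 (31.8), Olfr1425 (30.1), Mrpl23 (28.0) and Tmem216 (27.2), each listed at 0 in both Yy1 hairpin libraries. Tmem258 (99.9 and 168 FPKM), Gstp1 (29.1 and 41.6), Cdc26 (19.1 and 55.3) and Olfr545 (35.2 and 38.2) were listed at 0 in the control and present in both hairpin libraries, as was Epb41l4aos. Ribosomal proteins had a median of -0.75 (79 of 84 below 0; camera adjusted p = 3.7e-16), and glycolysis and hypoxia -0.53 (adjusted p = 0.0077). The median was -0.49 for core pluripotency (13 of 14 below 0; adjusted p = 0.011), -0.40 for S phase (adjusted p = 0.013) and -0.66 for DNA methylation machinery (adjusted p = 0.017). With an estimated correlation the adjusted p was 0.35 for core pluripotency and DNA methylation and 0.66 for the other 3. The hairpin libraries had 11397 and 11220 genes above 0 and ribosomal protein medians of 278 and 295 FPKM, against 11760 genes and 565 FPKM in their control. Low values of both kinds were also found in the EPSC control (11246 genes, 255 FPKM) and in 3sgMIR (11197 genes, 312 FPKM), so the Yy1 lists are not separated from a difference between libraries. No member of these lists passed, over all genes or adjusted over the list alone. Rpl34 (-3.12), Trim28 (-1.22), Lin28a (-1.09), Cdt1 (-2.60) and Dnmt3l (-1.75) are examples of their values. The 2-fold changes of the simulated data were recovered for 1% of genes here, so changes of that size were mostly not detectable in these libraries.

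Guides titled sgMIR were compared with scrambled guides to ask which transcripts depend on MIR regions. Of 13800 genes 1 passed, and 615 had an unadjusted p under the threshold, not more than chance alone would give. That gene was Cox7a1, a muscle-type subunit of cytochrome c oxidase, at 37.8 and 20.5 FPKM with scrambled guides and listed at 0 with all 3 sgMIR libraries (adjusted p = 0.039). It was also listed at 0 in the other 6 libraries of the set, and in fits leaving out 1 of the 5 guide libraries no gene passed with limma. The adjusted p of Cox7a1 was 0.10, 0.17 and 0.25 without sgMIR replicates 1, 2 and 3. Two-cell-like genes had a median of -0.79 (17 of 18 below 0; camera adjusted p = 0.019), endoderm genes -0.68 (adjusted p = 0.016), p53 targets -0.51 (adjusted p = 0.017) and ribosomal proteins -0.30 (adjusted p = 0.0083). Each had adjusted p = 0.81 with an estimated correlation and 0 members past the threshold, over all genes or adjusted over the list alone. The ribosomal protein value came from 1 library: against the ESC control, 3sgMIR was at -0.81, sgMIR22 at -0.05, sgMIR23 at 0.01 and the scrambled guides at -0.015 and 0.00. Values of members were -2.22 for Usp17lb, -1.46 for Dux, -1.95 for Pltp, -1.38 for Plk2 and -1.26 for Rpl34. The endoderm factors Foxa1 (2.47 and 1.48 FPKM with scrambled guides) and Gata4 (6.44 and 1.31) were listed at 0 with all 3 sgMIR libraries. In this set 1 fragment of a 2 kb transcript is worth an estimated 1.37 to 2.16 FPKM. Most of these levels are near that, so the 0 values cannot show a loss. The median over all genes was -0.12 and moved by 0.16 under median centring, and these lists stayed below 0 there. Of simulated 2-fold changes 11% were recovered here, so changes of that size were mostly not detectable in these libraries. The labels do not state which MIR regions the guides target. The libraries are titled 3sgMIR, sgMIR22 and sgMIR23, the meaning of the leading digit is not given, and they were taken as 1 group.

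Changes with sgMIR guides were set beside those of Esrrb knockdown, since the series links Esrrb with MIR elements. Cox7a1 fell in both media of the first set as well, and was the 1 shared call with 2i and the 1 shared call with LS; with EPSCs there was 0. At an unadjusted p under the threshold and a log2 change of 0.5, 10 genes were higher in both sgMIR and 2i, 18 lower in both and 36 opposite, where independent lists would give 7.85, 14.3 and 24.5. With LS the counts were 6, 27 and 38 (9.01, 25.5 and 32.0 for independent lists). With EPSCs they were 19, 24 and 69 (12.0, 13.9 and 33.4), above these numbers in each direction; both comparisons come from the same fit. Log2 changes correlated across genes at -0.018, -0.050 and -0.075.

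The EPSC empty vector differed from the empty vector without a named medium in 4 of 13800 genes, 1 higher and 3 lower, with 1357 at an unadjusted p under the threshold. Each side is 1 library, and the count depends on the pseudocount and the filter, as given below. Trh was at 276 FPKM in the ESC control and 10.8 FPKM in EPSCs (log2 change -4.55, SE 0.46, adjusted p = 0.022), and at 23.2 and 32.3 FPKM in the EPSC hairpin libraries. The ubiquitin-conjugating enzyme Ube2a was at 48.3 and the repair factor Gtf2h5 at 31.9 FPKM, both listed at 0 in the EPSC control. Gtf2h5 was present in both EPSC hairpin libraries and rose in the EPSC knockdown, so that call and this one rest on the same 0. The predicted gene Gm10857, named after its values were seen, was listed at 0 in the ESC control and at 60.1 FPKM in the EPSC control. Pluripotency lists were lower in this 1 EPSC control library than in the 1 ESC control library. Core genes had a median of -0.77 (camera adjusted p = 8.3e-05, and adjusted p = 0.086 with an estimated correlation; 3 of 14 lower adjusted over the list alone). Naive genes had -0.56 (adjusted p = 0.0059, and adjusted p = 0.47 with an estimated correlation; 1 of 25). Lin28a was at 70.1 and 5.14 FPKM but at 41.4 and 44.9 FPKM in the EPSC hairpin libraries. Nr0b1 was at 44.3 FPKM and listed at 0, and at 17.8 and 4.35 FPKM in the hairpin libraries. Glycolysis and hypoxia genes had a median of -1.51 (adjusted p = 1.7e-07, and adjusted p = 0.15 with an estimated correlation; 10 of 24 lower adjusted over the list alone), with Ldha at 331 and 37.3 FPKM. Germline genes silenced by methylation had a median of 1.16 (adjusted p = 2.5e-04, and adjusted p = 0.086 with an estimated correlation; 1 of 20 higher adjusted over the list alone), with Hormad1 listed at 0 in the ESC control, at 17.7 FPKM in the EPSC control and at 6.11 to 12.7 FPKM in the other 9 libraries.

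ERK targets had a median of -1.24 (adjusted p = 0.0079, and adjusted p = 0.17 with an estimated correlation), with Egr1 at 15.0 and Spry4 at 20.9 FPKM in the ESC control and both listed at 0 in the EPSC control. In the EPSC knockdown, against the same control, the ERK median was 0.89 and did not pass camera. Ribosomal proteins had a median of -0.92 (80 of 84 below 0; adjusted p = 8.0e-16), two-cell-like genes -0.80 (adjusted p = 0.033), oxidative phosphorylation -0.31 (adjusted p = 0.017) and endoderm genes 0.22 (adjusted p = 0.040), at adjusted p = 0.47, 0.47, 0.52 and 0.47 with an estimated correlation. Rpl34 was at 208 and 5.97 FPKM, Zscan4d at 7.27 FPKM and listed at 0, Ndufv3 at 81.2 and 1.44 FPKM, and Gata6 had a log2 change of 2.82. No member of these lists passed over all genes. Median centring moved the median over all genes by 0.10, and these lists kept their direction. The median FPKM of ribosomal proteins was 255 in the EPSC control and 565 in the ESC control, and it also differed within the sgMIR group.

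**Figure D3:**
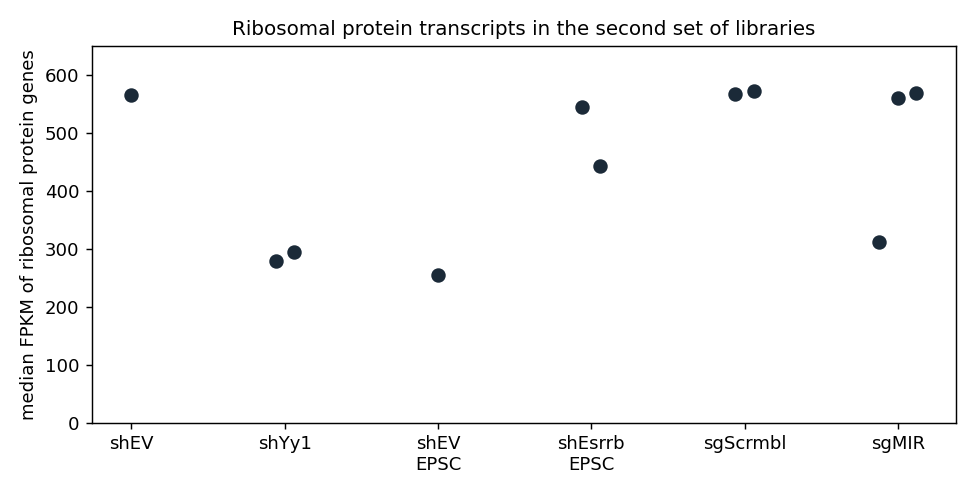
Median FPKM of 84 ribosomal protein genes (vertical axis) in each of the 11 libraries of the second set, by group; each point is 1 library. Values lie at 255 in the EPSC control, 278 and 295 with Yy1 hairpins and 312 in 1 sgMIR library, and at 444 to 572 in the other 7 libraries.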

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

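The test of LS genes in the EPSC knockdown was added after the data were seen, before its own result was known; the other tests in this part were chosen before their results were seen.

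Esrrb knockdown did not act alike in 2i and LS for 13 genes, by a test of the difference between the responses. Zfp57, a protector of imprints (log2 difference 1.14), the phosphatase Acp6 (1.44), the myosin light chain Mylpf (1.85) and Pisd-ps1 (3.59) responded higher in 2i than in LS. The Hedgehog receptor Ptch1 (-2.16), Spats2l (-2.26), Bend3 (-1.50) and the ubiquitin ligase subunit Rnf7 (-1.12) responded lower. Pisd-ps1 is a pseudogene with near-identical relatives, so its own level is uncertain. Leaving out either hairpin library of 2i, which leaves 1 library in that group, most of these named genes lost their call. Those tested kept their direction there and without either hairpin library of LS. With a replicate block for hairpin number 637 passed, 394 of them higher in 2i. By camera, the difference passed for 6 lists, with medians of 0.44 for naive pluripotency, -0.54 for formative and primed pluripotency, 0.94 for mesoderm and primitive streak, 1.13 for two-cell-like, 0.086 for oxidative phosphorylation and 0.32 for glycolysis and hypoxia genes. With an estimated correlation no list passed (smallest adjusted p = 0.73).

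Naive pluripotency genes fell in LS and less so in 2i: Tbx3 had log2 changes of -1.99 and -0.29, while Nr0b1 (-1.02 in LS and -2.38 in 2i) and Tcl1 (-1.22 and -2.04) went the other way, so the pattern holds for the list median and not for every member. A weaker knockdown in 2i would leave few genes responding more there. Of 1875 genes changed on the average over media, 11.89% responded more in 2i and 18.72% more in LS, where chance gives 2.5%. That 2.5% assumes no real difference at any gene, and 1818 of all 12347 genes had an unadjusted p under 0.05 for the difference. The shares therefore cannot decide. Esrrb was at 11.1% and 15.7% of its control in 2i and at 11.4% and 28.1% in LS. By transcript level, then, the knockdown was not weaker in 2i. An aberrant LS control stays open. The 608 LS genes that fell had a median of -0.10 in the EPSC knockdown, at percentile 0 of 10000 matched lists. Random lists carry no correlation between genes. Camera with an estimated correlation gave an adjusted p of 0.11, but has little power with few residual degrees of freedom. Neither test can decide. The inhibitors of 2i may also keep naive genes active when Esrrb is low, which was not tested.

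Short RNA genes lead the difference between media: 5 of the 13 genes are 300 nt or shorter, against 35 of the tested genes (0.286%). Of 22 such genes with a mean of at least 10 FPKM, 14 (63.64%) fell below 0.1 FPKM in at least 1 library, against 0 of 6471 longer genes. Unstable estimates of genes shorter than a fragment are a candidate explanation for these 5 calls. The other 8 genes are longer. No biological explanation was tested for the short genes.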

How the results depend on the processing

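The filter at FPKM 20, the library quality weights and the fits of 2i against LS without an empty vector were tests chosen after the data were seen. Among single named genes, 3477 values kept their direction and side of the threshold, 441 lost the call in the same direction, 30 gained it and 2 changed sign. Those were Hist1h1c in 2i (-0.014 in the additive model) and the difference of Esrrb between media (0.20 without shEsrrb_LS replicate 2 and -1.07 without replicate 1). The additive model gives 1 effect over both media, and Hist1h1c had log2 changes of 0.59 in 2i and -0.61 in LS. Without shEsrrb_LS replicate 2, the log2 change of Esrrb in LS was -3.08, below its -2.88 in 2i. For 2i against LS every alternative run stayed within 1.5 times of 6823 genes, from 5250 (filter at FPKM 5) to 7589 (replicate block).

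With no filter, 5 genes passed in 2i, 1 in LS, 2 for the difference between media, 22 in EPSCs and 10 for sgMIR; the prior of limma then gave 4.07 total degrees of freedom in LS and 2i in place of 6.84. Esrrb kept its log2 change of -2.88 in 2i and -2.45 in LS with no filter (adjusted p = 0.16 and 0.13) and with robust variances (-2.88 and -2.45, adjusted p = 0.23 and 0.19). Robust variances gave 20 genes for the difference and 0 for sgMIR. Quantile normalization gave 4 for the difference and 0 for EPSCs, and median centring 0 for EPSCs. Centring also gave 244 higher and 299 lower genes in 2i, against 325 and 267, and 3014 and 3825 for 2i against LS, against 3671 and 3152. The replicate block gave 1466, 2804 and 637 genes for 2i, LS and the difference. The block rests on hairpin number alone: hairpin differences correlated across genes at 0.18 between 2i and LS, 0.065 and 0.039 with EPSCs. The cause of these moves was not tested.

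A pseudocount of 0.1 gave 79 genes for EPSCs (70 higher), 23 for Yy1, 0 for sgMIR and 61 for EPSCs against ESCs. The filter at FPKM 5 gave 8, 0 and 11 for EPSCs, sgMIR and EPSCs against ESCs, and that at FPKM 20 gave 12, 0 and 9. Quality weights gave 11 for EPSCs and 2 for sgMIR. Fits to the compared groups only gave 69 for EPSCs (66 higher), 44 for Yy1 and 0 for sgMIR. For sgMIR, the title format term gave 0, the libraries sgMIR22 and sgMIR23 alone 0, and 3sgMIR alone 7. Beside the counts of 0 by limma stand 1343 genes in EPSCs and 615 for sgMIR at an unadjusted p under 0.05. Chance alone would bring a share of 0.05 of the 13800 tested genes to that level, which the count for sgMIR does not exceed.

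Leaving out 1 library, where a lone library is assumed to vary like the other groups, gave 221 to 236 genes in 2i, 371 (without shEsrrb_LS replicate 1) to 1145 in LS, 4 to 40 for the difference, 0 for EPSCs and 0 for sgMIR. Esrrb ranged from -3.13 to -2.64 in 2i, with adjusted p = 0.060 and 0.088, and from -3.08 to -1.81 in LS.

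With an estimated correlation, which has little power on few residual degrees of freedom, 0 lists passed camera in each of the 8 comparisons. Directional fry gave 1 list in 2i, 0 in LS, 1 for the difference, 19 for 2i against LS, 0 for EPSCs, 0 for Yy1, 0 for sgMIR and 3 for EPSCs against ESCs, and mixed fry 21 in LS, 17 for the difference, 26 for 2i against LS and 8 for EPSCs. At an unadjusted p under 0.05 and a log2 change of 0.5, sgMIR shared 28, 33 and 43 genes in direction with 2i, LS and EPSCs. At the depth of the second set, 1 fragment of a 2 kb transcript equals an estimated 1.37 to 2.16 FPKM, so low values there rest on few fragments. No alternative varied the depth.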

Other observations

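The tests on ribosomal proteins and those of LS and 2i genes as sets in other comparisons were chosen after the data were seen; the test over splits was chosen before.

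Genes that Esrrb knockdown moved in LS and 2i leaned the same way in EPSCs. Each value is set against the single EPSC control library, which had low ribosomal protein values. A shift of that library would enter all of them. The 535 genes that rose in LS had a median log2 change of 0.59 in the EPSC knockdown and the 296 that rose in 2i had 0.61, both at percentile 100 of 10000 matched lists. The 608 that fell in LS had -0.10 and the 249 that fell in 2i had -0.17, both at percentile 0. Camera adjusted p were 2.5e-05, 9.6e-04, 6.6e-04 and 4.6e-05, and 0.33, 0.27, 0.11 and 0.16 with an estimated correlation. Nanog was at 237 FPKM in the EPSC control and at 78.8 and 77.6 FPKM with hairpins (log2 change -1.59, adjusted p = 0.088, which did not pass).

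With sgMIR guides the median over all genes was -0.12. The same sets gave -0.21 for genes that rose in LS (percentile 0) and -0.23 for those that rose in 2i (percentile 0.75). These lay somewhat below the median over all genes, and the matched lists carry no correlation between genes. The sets that fell in LS and 2i gave -0.11 and -0.13 (percentiles 57.0 and 32.3), near that median. None passed camera (smallest adjusted p = 0.11). After Yy1 knockdown all 4 sets had medians below 0, whichever way they moved after Esrrb knockdown. Genes that fell in LS had -0.30 (camera adjusted p = 0.031, and 0.17 with an estimated correlation) and those that rose in LS -0.18. Genes that fell in 2i had -0.25 and those that rose in 2i -0.13. The set that rose in 2i lay at percentile 5.52, within the range of its matched lists. Only the set that fell in LS passed camera. Crip1, chosen after its values were seen, was at 13.7, 19.9 and 21.2 FPKM with sgMIR guides and listed at 0 in the other 8 libraries of the set (adjusted p = 0.067).

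Single genes from lists that did not pass camera also changed after Esrrb knockdown, in both directions. In LS the growth factor receptor Fgfr2 (log2 change 1.29), Id2 (1.61) and the neural factor Sox11 (0.99) rose, and Cdx1 (-1.82), Tead4 (-0.96), Ncam1 (-1.24) and the ERK target Etv4 (-1.16) fell. In 2i the trophoblast regulator Tfap2c (-1.75) and the laminin Lama1 (-1.97) fell and Serpinh1 (1.28) and the retinoic acid receptor Rarg (0.94) rose.

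In 2i against LS, a fit with 2 groups gave 4313 changed genes for the real split of the 6 libraries, and the highest other split gave 1, so 1 of 10 splits was as large. With 10 splits, no share under 0.05 can be reached.

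Ribosomal protein genes were lower in the EPSC control than in the ESC control, with a median of -0.92. A loss of short transcripts would lower other genes of like length and level as well. The median lay at percentile 0 of 10000 matched lists (middle range -0.46 to -0.07). These lists were matched in coarse classes of expression and of the longest transcript of a gene, and carry no correlation between genes. They therefore cannot decide whether short transcripts were lost. Other well-expressed genes of the shortest length class had a median of -0.31, so short transcripts were lower in part. The EPSC hairpin libraries lay at -0.242, so the single EPSC control library may differ on its own, but these libraries also carry the knockdown. The 3sgMIR library lay at -0.8112 while its group partners lay at -0.05 and 0.01, so a shift of single libraries that is not tied to the condition stays open too, and it stays open for the Yy1 hairpin libraries (-0.75 and -0.81) as well. These explanations and a biological one, the EPSC medium, cannot be told apart with 1 control library.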
